A study of Mus musculus with 3 samples.

How the data were processed

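Binding of Foxp3 was assayed by CUT&RUN in mouse bone marrow-derived macrophages (BMDMs), which are macrophages grown from bone marrow progenitors in medium conditioned with the growth factor M-CSF. In CUT&RUN, an antibody directs a nuclease to the sites of its target in permeabilised cells, and the short DNA fragments that are cut free are sequenced. Per the labels' protocols, cells were fixed in 0.1% formaldehyde for 2 min and fragments were released with a commercial kit and a Foxp3 antibody. The series title names stimulation with damage-associated molecules from brain, and the sample labels do not say which libraries received it. The series holds 3 samples, of which 2 are Foxp3 libraries (replicates 1 and 2) and 1 is a library made with an isotype IgG. Peak lists of the 2 Foxp3 libraries were analysed. No values of the IgG library were used here, so no comparison with background was possible. The labels do not say whether the replicates came from separate cultures or animals, and the spread between them may therefore be technical.

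Per the submitters' processing notes, CASAVA 1.4 was used and the genome build was mm10. The aligner is not given in the sources used here. Per the file headers, peaks were called by the authors with MACS 2.1.1.20160309 in paired-end mode, on each library separately, at a q-value cutoff of 0.01 and an effective genome size of 1.87e+09 bp. Per the file headers, no control library entered the calling and all duplicate fragments were kept. A site that gives fragments with any antibody, or a fragment amplified many times, can therefore be listed as a peak. The deposited pileup is a signal, the number of fragments over the summit, and it was not scaled to depth. The deposited fold enrichment is the ratio of that pileup plus 1 to a background term estimated from the same library, either genome-wide or over the surrounding 10000 bp. The deposited significance of each peak is given as −log10 of a p-value and −log10 of a q-value. Positions were deposited as 1-based coordinates. In both lists every length equalled end minus start plus 1, no peaks of a list overlapped, and every pileup was a whole number.

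Per the file headers, replicate 1 held 33294105 fragments with a fragment size of 130 bp, and replicate 2 held 34898401 fragments with a fragment size of 180 bp. The smallest pileup called was 10 fragments in replicate 1 and 13 in replicate 2, and weaker sites could not be listed. Intervals given for shares are 95% exact binomial (Clopper-Pearson) intervals and cover counting error only.

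Gene names and gene positions came from a RefSeq table of the GRCm38.p6 assembly, whose coordinates on chromosomes 1 to 19 and X are those of mm10. That table gives the start and end of each gene without its strand, so the transcription start could not be told from the other end. Where a test at transcription starts had been planned, it was run on both annotated ends of the gene. A gene was counted as having a site when a peak overlapped the window of 1000 bp on either side of either end, and a peak was counted as lying at a gene end when its summit was within 1000 bp of one. The 21627 protein-coding genes on the 19 autosomes and X were used. No genome sequence was used, and the planned search for forkhead, PU.1, AP-1 and CTCF sequence words was not run.

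Peaks were called shared when they overlapped by at least 50% of both lengths. Where a 1 bp overlap was used, a peak was paired with the peak it overlapped most. Chance was estimated from 100 placements of each list at random on the same chromosomes with sizes kept. As a local reference, replicate 2 peaks were also moved by 10 kb in both directions, and windows 20 kb outside both ends of each gene were examined. Windows that fell on the ends of other genes were kept, so these shares also reflect neighbouring genes. The strength of shared peaks was compared by Spearman's rho across peaks, which are not independent replicates, and no p-value was computed. For each of 14 gene lists, a two-sided Fisher's exact test compared members with all other protein-coding genes, with and without a site in both replicates, and p-values were adjusted over the 14 lists by Benjamini-Hochberg. These tests count genes, which are not replicates. Of the 379 list entries, 377 were matched, and Mx1 and Mx2 were left out because the table does not class them as protein-coding.

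The lists, the tests, the main settings, most alternatives and the rule for the genes to be named were fixed before the data were examined. The rule named Rubcn and Foxp3 always, then the 15 genes with the highest mean of the within-list percentiles of fold enrichment in the replicates, then the 3 highest members of each list. Alternatives were windows of 5000 bp, whole gene bodies, a 1 bp overlap, stricter peaks, the strongest peaks of replicate 1 in the number that replicate 2 holds, each replicate alone, and the housekeeping list as background. With no strand known, the gene body alternative extended 5000 bp at both ends. Added once the data had been seen were the 10 kb shift, the 20 kb windows, a common smallest pileup and a removal of peaks with a pileup of at least 1000. The plan did not say by which value the strongest peaks were to be ranked. Fold enrichment was taken, as for strength elsewhere, and a ranking by −log10 q was added last, when the results by fold were known.

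The procedures were tested on simulated data with the real peak sizes at random places. All 200 seeded genes were recovered in a simulation of 21627 genes, and 28 other genes were gained because their ends lay beside a seeded one. The seeded peaks were placed inside the windows in both lists. Their recovery therefore checks the counting only and does not measure sensitivity to real sites. With the real gene calls, 4.4% of 500 random lists of 28 genes had an unadjusted p below 0.05, and 94% of lists with a true share of 90% did. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.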

Results

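Foxp3 is a forkhead transcription factor best known from regulatory T cells. Its occupancy was profiled here in BMDMs, with 2 Foxp3 libraries sequenced to 33294105 and 34898401 fragments. The first question was which genomic sites were recovered, and whether both replicates recovered them. Replicate 1 gave 556535 peaks covering 119 Mb, with a median length of 167 bp. Replicate 2 gave 95135 peaks covering 30.2 Mb, with a median length of 236 bp. Replicate 1 thus held 5.85 times as many peaks at 0.954 times the fragments. The fragments over peak summits came to 45.0% of all fragments in replicate 1 and 9.82% in replicate 2. Without peaks of at least 1000 fragments, these shares were 44.4% and 6.70%. Median fold enrichment, the summit pileup plus 1 over the background term of the same library as MACS2 gave it, was 4.92 in replicate 1 and 3.99 in replicate 2. All fold enrichments below are these deposited values, and no IgG value stands beside them.

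The replicates shared 31253 peaks. These were 32.9% of replicate 2 peaks (95% interval 32.6 to 33.2%) and 5.62% of replicate 1 peaks (5.56 to 5.68%). Random placement of replicate 2 peaks gave 2.97% ± 0.057 (SD over 100 placements), and moving them by 10 kb gave 4.28%, so the observed share was 11.1 and 7.68 times these references. Sharing was more frequent among stronger peaks. Of the strongest 10% of replicate 2 peaks, 74.6% were shared, against 16.4% of the weakest 10%. In replicate 1 these shares were 25.6% and 1.34%. Across the shared peaks the fold enrichments of the replicates had a Spearman's rho of 0.50. When replicate 1 was restricted to its strongest peaks, as many as replicate 2 holds, 18.95% of replicate 2 peaks were shared with ranking by fold and 20.2% with ranking by −log10 q.

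The second comparison asked where the sites lay relative to genes. The shared peaks were concentrated at the ends of protein-coding genes. Of 31111 shared peaks on the autosomes and X, 8626 (27.7%, 95% interval 27.2 to 28.2%) had a summit within 1 kb of an annotated gene end, which was 8.76 times the 3.17% ± 0.082 of random placements. The share was 15.1% in replicate 2 (14.9 to 15.4%) and 5.96% in replicate 1 (5.90 to 6.03%), which were 4.79 and 1.90 times random placement. The strongest peaks of replicate 1, taken in the number that replicate 2 holds, gave 12.9% with ranking by fold and 15.1% with ranking by −log10 q. Shared peaks at gene ends had a median fold enrichment of 5.59 in replicate 2, against 4.37 for shared peaks elsewhere. A further 35.2% of shared peaks lay inside genes away from their ends, below the 39.0% of random placements, and 37.1% lay between genes.

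**Figure D1:**
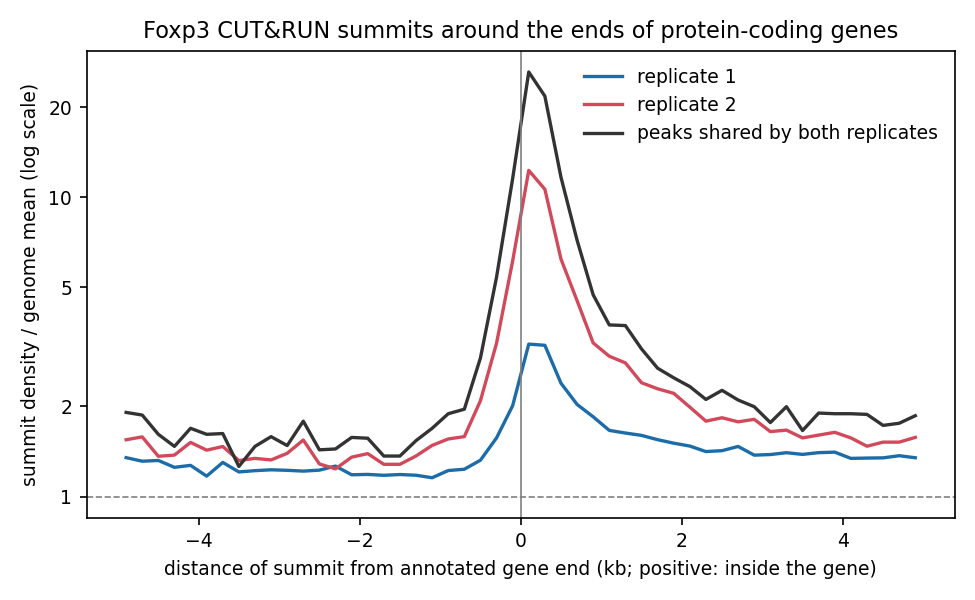
Density of peak summits in 200 bp bins around both annotated ends of 21627 protein-coding genes, divided by the mean density over the chromosomes (log axis); the x axis is the distance from the gene end in kb, positive inside the gene, and lines are replicate 1, replicate 2 and the shared peaks. The highest bin lay just inside the gene, at 26.2 times the mean for shared peaks, 12.3 times for replicate 2 and 3.23 times for replicate 1.

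Summit density peaked just inside the gene. In the first 200 bp inside gene ends it was 26.2 times the chromosome mean for shared peaks, 12.3 times for replicate 2 and 3.23 times for replicate 1. It fell to 11.5 times for shared peaks in the first 200 bp outside. The gene table carries no strand, so transcription starts and the opposite ends were pooled in these values.

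At the level of genes, 13459 of 21627 protein-coding genes (62.2%) had a peak within 1 kb of an end in both replicates. Random placement of both lists gave 2120 genes on average and at most 2273. Replicate 1 alone had 18621 such genes, against 13162 by chance, and replicate 2 alone had 13693, against 3408 by chance. The peaks of the replicates did not have to overlap or lie at the same end of the gene. Replicate 1 had a site at 86.1% of genes, against 60.9% by chance. The count in both replicates was therefore close to that of replicate 2 alone and says little about repeatability. A site in both replicates was thus found at most genes and in itself singles out few. Windows 20 kb outside the genes held peaks of both replicates for 21.9% of genes.

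Rubcn, which encodes Rubicon, a protein required for LC3-associated phagocytosis, was examined first because the study of Foxp3 in macrophages concerns the uptake of debris. Rubcn (gene ID 100502698) spans chromosome 16, positions 32821702 to 32877729, in mm10. Both replicates had a peak at its higher-coordinate end, from 32877398 to 32877881 in replicate 1 and from 32877451 to 32877886 in replicate 2. Its fold enrichment was 21.9 in replicate 1 and 5.50 in replicate 2 (mean 13.7 ± 11.6, SD, n = 2), with summit pileups of 150 and 27 fragments. Among the 13459 genes with a site in both replicates, 95.6% had an equal or lower fold in replicate 1 and 53.0% in replicate 2. The same peak covers the lower end of the neighbouring gene Fyttd1, which begins at position 32877581, so it could not be assigned to Rubcn alone. A second pair of overlapping peaks, which did not reach 50% of both lengths, lay inside Rubcn, with summits at 32868159 and 32868202 and fold enrichments of 19.1 and 5.50. In all, 19 peaks of replicate 1 and 6 of replicate 2 lay over Rubcn and the 5 kb around it, and 2 of each overlapped the other replicate.

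**Figure D2:**
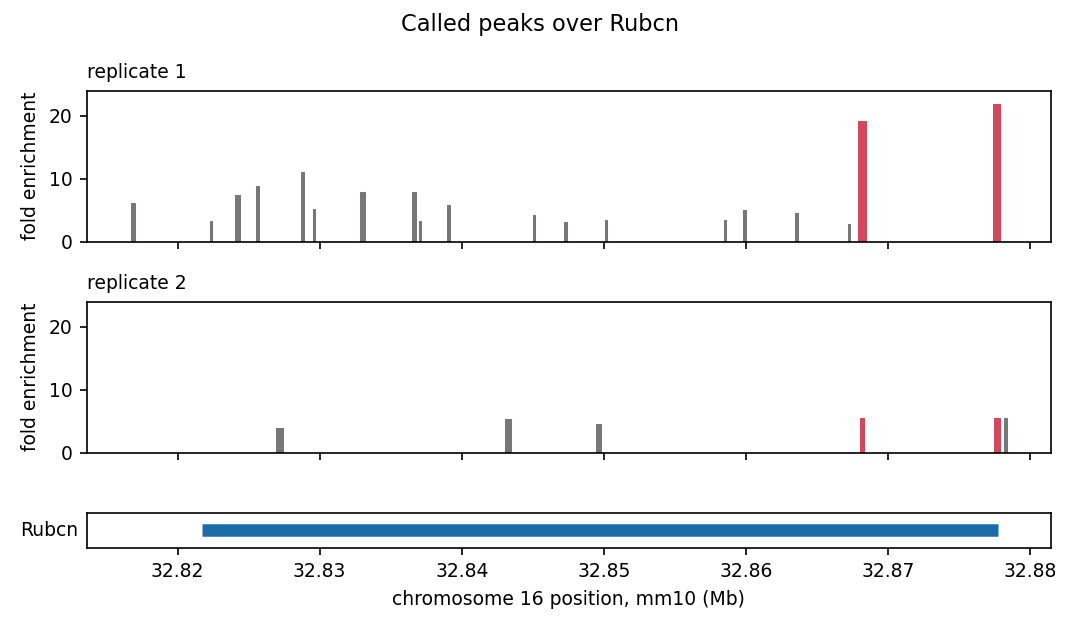
Called peaks over Rubcn and 5 kb on either side; the x axis is the position on chromosome 16 in Mb (mm10), bar width is the peak's extent, bar height is the deposited fold enrichment, and red bars overlap a peak of the other replicate by at least 1 bp. The 2 overlapping pairs reached 19.1 and 21.9 in replicate 1 and 5.50 each in replicate 2.

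The Foxp3 gene itself (gene ID 20371, chromosome X, positions 7579676 to 7595243) carried no peak in replicate 2 within 5 kb. Replicate 1 had 9 peaks there, with fold enrichments from 2.82 to 14.7 and a median of 4.49.

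The 15 genes with the strongest sites in both replicates were a mixture without a common function by name. Lars2, the mitochondrial leucyl-tRNA synthetase, led with fold enrichments of 34.1 and 32.6 in replicates 1 and 2, followed by 2210016F16Rik with 35.1 and 11.8. Sspn, which encodes sarcospan of the dystrophin complex, had 25.5 and 24.03. Wls, the carrier for Wnt secretion, had 27.0 and 12.4, and Smpdl3a, a phosphodiesterase related to acid sphingomyelinase, had 24.3 and 12.8. Exosc3 of the RNA exosome had 26.8 and 10.5, Atic of purine synthesis had 27.0 and 10.4, and the translation initiation factor gene Eif3j1 had 25.4 and 10.6. Bbs7 of the ciliary BBSome had 25.6 and 10.5, and the desmosomal plakophilin gene Pkp2 had 27.4 and 10.1. The remaining members were Gm52416 (26.5 and 11.6), Nit2 (26.6 and 10.7), Vmn2r29 (22.9 and 14.8), Tent2 (25.3 and 10.6) and Pcnx4 (29.8 and 10.0). In all 15 genes the strongest peaks of the replicates overlapped by at least 1 bp. Both Sspn summits lay 1048 bp from its nearest end, so its site counts only because the peaks overlapped the window. The Wls summits lay 896 and 891 bp beyond its end. Lars2 and Sspn had summit pileups of 462 and 296 fragments in replicate 1 and 690 and 257 in replicate 2, against a median pileup of 21 in either list. No screen for repeats was applied and no IgG values were used. It is therefore unknown whether these or the other sites depend on the Foxp3 antibody. Vmn2r29 belongs to a multigene family whose copies can share reads, so its value is uncertain.

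The third comparison asked whether gene groups fitting macrophage uptake of debris, macrophage identity or the Foxp3 programme of regulatory T cells carried sites more often than other genes. Of the 14 lists, the forkhead family and the lysosome list had a site in both replicates more often than other genes after adjustment, and no list had one less often. Before adjustment, 6 lists had p below 0.05, with 4 higher and 2 lower. Every list is set below against all other protein-coding genes, of which about 62.2% had a site. Those include 1106 olfactory and 353 vomeronasal receptor genes, of which only 3.62% and 2.55% had one. The lists were not tested without these receptor genes, so it is unknown whether the calls depend on them.

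Forkhead genes, relatives of Foxp3 itself, carried a site in 27 of 28 cases (96.4%, 95% interval 81.7 to 99.9%; Fisher's exact test, adjusted p = 0.000604). The strongest were Foxm1, a cell cycle regulator, with fold enrichments of 19.2 and 7.04, Foxj3 with 12.4 and 8.97, and Foxa3 with 12.7 and 6.68. All 3 peaks also lay at the end of a neighbouring gene (Rhno1, Frg2f1 and Sympk in that order), and the Foxa3 summits lay 838 and 1102 bp beyond its end, so none could be assigned to the forkhead gene alone. Foxa1 was the exception, with a site in replicate 1 only. At windows 20 kb outside these genes the share was 14.3%. With the strongest peaks of replicate 1 in equal number, the call was lost when they were ranked by fold (17 of 28 genes, Fisher's exact test, adjusted p = 0.33) and held when they were ranked by −log10 q (26 of 28, adjusted p = 0.000164). It was also lost with replicate 1 alone, where all 28 had a site but so did 86.1% of all genes (Fisher's exact test, adjusted p = 0.30), and with whole gene bodies (28 of 28, adjusted p = 0.0685). The difference from other genes was 34.2 percentage points, 13.9 with replicate 1 alone and 17.3 with gene bodies.

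Genes of the lysosome, the compartment that digests engulfed material, carried a site in 26 of 30 cases (86.7%, 69.3 to 96.2%; Fisher's exact test, adjusted p = 0.0309). The protease gene Ctsl had fold enrichments of 17.3 and 8.71, and the vacuolar ATPase subunit genes Atp6v1h and Atp6v1a, which serve lysosomal acidification, had 15.9 and 8.25 and 17.4 and 6.56. The Atp6v1a peaks of the replicates did not overlap and lay near the end of Naa50 as well. Ctss, Atp6v0d2 and Gusb were among those without a site in both. Windows 20 kb outside the lysosome genes held both replicates' peaks for 40.0%, above the 21.9% of all genes. The difference from other genes was 24.5 percentage points. With replicate 2 alone it was nearly as large at 23.4 points but just missed the threshold (Fisher's exact test, adjusted p = 0.0502), and the call was also lost with replicate 1 alone (10.6 points, adjusted p = 0.30) and with whole gene bodies (17.3 points, 30 of 30 genes, adjusted p = 0.0685). With the strongest peaks of replicate 1 in equal number it was lost when they were ranked by fold (Fisher's exact test, adjusted p = 0.12) and held when they were ranked by −log10 q (adjusted p = 0.0357).

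The autophagy and phagocytosis lists lay above the other genes without passing the test. Genes of autophagy initiation and cargo receptors had a site in 17 of 19 cases (89.5%, 66.9 to 98.7%; Fisher's exact test, adjusted p = 0.0632), led by Tax1bp1 (19.1 and 9.23), Rb1cc1 (17.1 and 9.58) and Ulk2 (14.9 and 7.41). Sqstm1 and Calcoco1 were without one in replicate 2. LC3-associated phagocytosis genes, Rubcn among them, had a site in 18 of 22 cases (81.8%, 59.7 to 94.8%; adjusted p = 0.15 by Fisher's exact test). The conjugation genes Atg3 (19.3 and 7.64) and Atg12 (11.5 and 6.65) and the phosphoinositide-binding Wipi2 (11.2 and 8.23) were the strongest, the Atg3 and Atg12 peaks lying also at the ends of Slc35a5 and Ap3s1, and Pik3c3, Cybb and Ncf4 were among those that lacked a site in both. Phagocytic receptor and engulfment genes had a site in 22 of 32 cases (68.8%, 49.99 to 83.9%; adjusted p = 0.63 by Fisher's exact test), led by Pros1, a bridging ligand for apoptotic cells (18.6 and 9.42), Rac1 (20.8 and 8.21) and Elmo1 (11.5 and 6.96). The direction of this list was not stable, at -8.68 percentage points from other genes with the strongest peaks of replicate 1 ranked by fold, -4.04 with ranking by −log10 q and -14.6 against the housekeeping genes. The housekeeping genes, a reference for promoters active in most cells, had a site in 25 of 30 cases (83.3%, 65.3 to 94.4%; adjusted p = 0.0632 by Fisher's exact test), with Hprt (15.2 and 8.32), Cct4 (16.6 and 7.52) and Vps29 (19.4 and 6.73, a peak also at the end of Rad9b) strongest and Gapdh, B2m, Ywhaz, Tubb5 and Reep5 without one in both. The lysosome, autophagy, LC3-associated phagocytosis and forkhead lists did not differ detectably from the housekeeping genes. The differences were 3.33, 6.14, -1.52 and 13.1 percentage points. The smallest adjusted p among these comparisons was 0.68 (Fisher's exact test, adjusted over 7 list pairs that include others).

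Macrophage and immune response genes lay below the other genes without passing the test. Only the inflammatory list kept this direction with windows of 5000 bp and with gene bodies, where macrophage identity genes lay 6.84 and 6.61 percentage points above other genes, alternative activation genes 2.61 and 2.50 above and interferon response genes 0.289 and 0.65 above. Macrophage identity genes had a site in 15 of 28 cases (53.6%, 33.9 to 72.5%; Fisher's exact test, adjusted p = 0.39), led by Mitf (15.8 and 5.86), the galectin gene Lgals3 (12.5 and 6.08) and Emilin2 (14.8 and 5.72, at opposite ends of the gene). Inflammatory response genes had the lowest share, 15 of 35 (42.9%, 26.3 to 60.6%; adjusted p = 0.0632 by Fisher's exact test). Ptgs2, the inducible cyclooxygenase (17.7 and 7.66), Nfkb1 (13.8 and 6.67) and the chemokine gene Cxcl2 (9.79 and 7.85) were strongest. Among genes chosen after their values were seen, Tnf (5.09) and Il1b (6.08) had a site in replicate 1 only and Il6 had none. Alternative activation and repair genes had a site in 13 of 27 cases (48.1%, 28.7 to 68.1%; adjusted p = 0.26 by Fisher's exact test), with Tgfbr2 (22.2 and 6.06), Pparg (19.5 and 5.89, at opposite ends of the gene) and Stat3 (13.8 and 6.09) strongest. Arg1 (14.8) and Il10 (10.8), likewise chosen afterwards, had a site in replicate 1 only. Interferon response genes had a site in 14 of 24 cases (58.3%, 36.6 to 77.9%; adjusted p = 0.68 by Fisher's exact test), with Usp18 (25.1 and 8.44) and the DNA sensor gene Cgas (22.0 and 6.20, a peak also at the end of Mto1) among the strongest.

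Genes associated with Foxp3 in regulatory T cells had a site in 14 of 28 cases (50%, 30.6 to 69.4%), which was 12.2 percentage points below other genes (Fisher's exact test, adjusted p = 0.33). The ectonucleotidase genes Entpd1 (19.6 and 7.85, a peak also at the end of Tctn3) and Nt5e (10.5 and 7.86) and the phosphodiesterase gene Pde3b (12.8 and 8.92) were strongest. Il2ra (3.97) and Ctla4 (3.17), chosen after their values were seen, had a site in replicate 1 only. T cell markers had a site in 10 of 20 cases (50%, 27.2 to 72.8%; adjusted p = 0.33 by Fisher's exact test), with Skap1 (7.10 and 5.58), Cd2 (8.23 and 4.58) and Cd8a (13.8 and 4.02) strongest, and in these 3 genes the strongest peaks of the replicates did not overlap. B cell and neutrophil markers had a site in 9 of 20 cases (45.0%, 23.1 to 68.5%; adjusted p = 0.26 by Fisher's exact test), with Cr2 (12.4 and 6.48, at opposite ends of the gene) and Pax5 (14.4 and 5.18) among the strongest. Genes restricted to other tissues had a site in 15 of 34 cases (44.1%, 27.2 to 62.1%; adjusted p = 0.0787 by Fisher's exact test), led by Pomc (11.6 and 7.44), Lor (11.2 and 6.08) and Actc1 (9.59 and 6.35). With replicate 1 alone, the regulatory T cell list lay 6.77 percentage points above other genes and the T cell markers 13.9 points above, neither past the test (adjusted p = 0.73 and 0.30, Fisher's exact test).

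**Figure D3:**
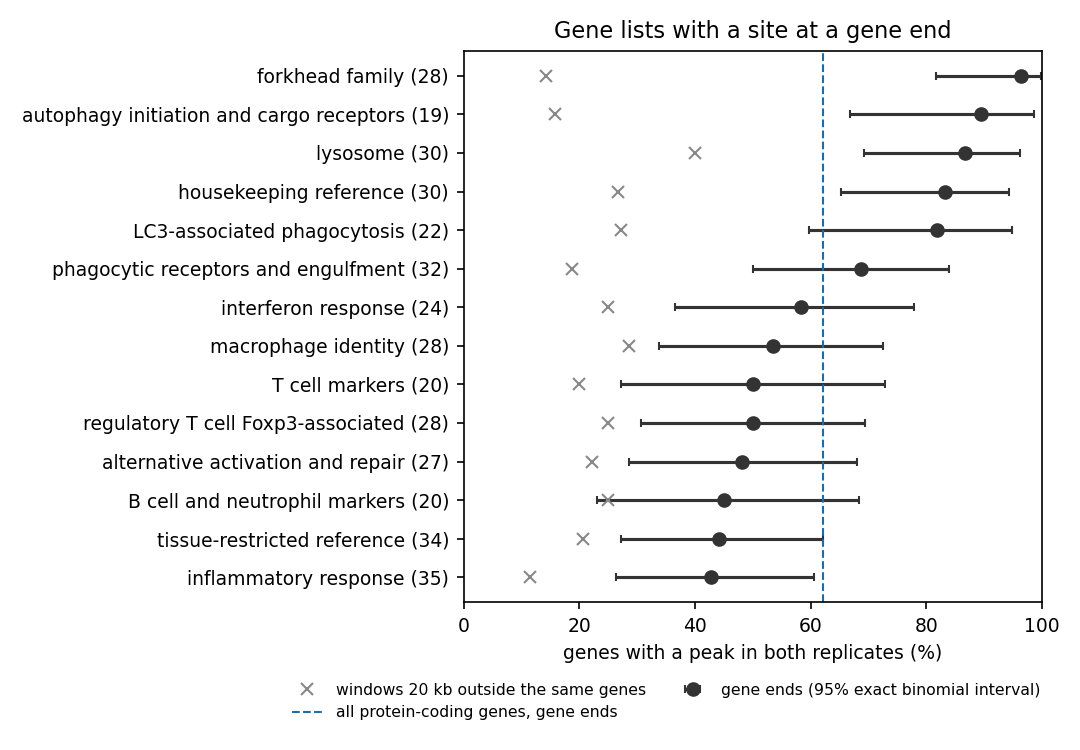
Share of each gene list with a peak in both replicates within 1 kb of a gene end (points, with 95% exact binomial intervals) and in windows 20 kb outside the same genes (crosses); the x axis is the percentage of genes, the number of members is in parentheses, and the dashed line is the 62.2% of all protein-coding genes. The forkhead family stands highest at 96.4% and the inflammatory response list lowest at 42.9%.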

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

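The tests in this part were devised after the patterns had been seen, except the planned comparison of the regulatory T cell list with other genes. The reading of that comparison as an explanation was set down afterwards. Of the other tests, only some were written down before their own values were seen. These were the common smallest pileup, the 20 kb windows for the forkhead and macrophage lists, and the Hox genes.

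Some peaks lay on sequence that the gene comparisons did not use, and they are given as counts without a test. On mitochondrial DNA, 11 peaks were listed in replicate 1 and 9 in replicate 2, with largest summit pileups of 305 and 294 fragments. On Y, 156 peaks were listed in replicate 1 and 32 in replicate 2. On unplaced sequence, the numbers were 834 and 275. No IgG values were at hand to set beside them.

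The highest summit pileup of both lists was at one site on chromosome 2, from 98666562 to 98667337 in replicate 1 and from 98666553 to 98667980 in replicate 2. It held 63908 fragments in replicate 1 and 659544 in replicate 2, a ratio of 10.3. Sequencing depth is excluded as the cause, since replicate 2 had 1.05 times the fragments of replicate 1. A general gain of pileup in replicate 2 is excluded too, because the other 51121 peaks of replicate 2 that overlapped a replicate 1 peak by at least 1 bp had a median ratio of 0.63, and so is a gain at every site with very high pileup, because the other 18 sites with at least 1000 fragments in both lists had a median ratio of 0.931. Those sites went both ways, with ratios of 7.31 on chromosome 12, 12.7 on chromosome 9 and 6.84 and 11.8 on chromosome 14, but 0.368 and 0.22 on chromosome 17 and 0.338 on chromosome 4, where replicate 1 held 11752, 7391 and 10201 fragments. Repeat copies collapsed in the genome build and duplicate fragments, which were all kept, were not tested, and neither was a biological difference between the replicates, whose stimulation and origin the labels do not give.

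Replicate 1 held 5.85 times the peaks of replicate 2. A difference in total fragments is excluded, with 0.954 times the fragments in replicate 1. These totals include all duplicate fragments, so the number of distinct fragments is not known and was not compared. A lower pileup needed for a call is excluded as the whole cause, since 5.08 times as many peaks remained at the smallest pileup called in replicate 2. Fewer fragments inside peaks in replicate 2 stay open, since the ratio of 4.58 between the shares of fragments over summits largely restates the number of peaks, with a median pileup of 21 in both lists. Without peaks of at least 1000 fragments that ratio was 6.62. The fragment size also differed, at 130 and 180 bp, and no biological explanation was tested.

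Gene lists differed in how often a site lay at a gene end in both replicates, among others between forkhead (96.4%) and macrophage identity genes (53.6%; Fisher's exact test, p = 0.000375), a pair chosen because it lay far apart, and activity of the genes in these cells stays open as the cause, as no expression was measured here. Regional density of peaks was examined for this pair at windows 20 kb outside the genes. There the forkhead list lay at -14.3 percentage points from the macrophage list, against 42.9 points at the gene ends. This argues against regional density for this pair but does not exclude it. The windows held peaks for only 4 and 8 of 28 genes and could fall on the ends of other genes. For the lysosome list regional density is a candidate explanation, since at those windows it lay 18.1 points above other genes (Fisher's exact test, p = 0.0252), against 24.5 points at the gene ends. A class of gene ends common to developmental regulators may contribute, but the Hox genes (69.2% of 39 genes) were not distinguishable from other genes (Fisher's exact test, p = 0.41). The Hox genes do not decide the question, as windows 20 kb outside them held peaks for 56.4%, against 21.9% of all genes. Among families chosen afterwards, Tbx (92.3%), Pax (88.9%) and Sox genes (84.2%) lay higher. Of these only the Tbx genes passed Fisher's exact test (adjusted p = 0.0419). Windows 20 kb outside them held peaks for 23.1% of Tbx, 55.6% of Pax and 15.8% of Sox genes. The Pax genes thus carry the same limit as the Hox genes. Recognition of the regulatory T cell targets of Foxp3 stays open as well, with that list at -12.2 percentage points and an interval that includes the share of other genes.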

How the results depend on the processing

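All alternatives here were planned, except the 10 kb shift, the common smallest pileup, the removal of peaks of at least 1000 fragments and the ranking by −log10 q. The plan did not say how the strongest peaks were to be ranked, and fold is meant below unless stated. The number of genes with a site in both replicates was 17059 with windows of 5000 bp and 10661 with the strongest peaks of replicate 1. Both stayed within 1.5 times the main value of 13459. Replicate 1 alone gave 18621 genes and replicate 2 alone 13693, which are not counts in both replicates. With peaks above the median −log10 q of both lists, replicate 1 kept 292174 peaks and replicate 2 30531. The share of replicate 2 peaks that were shared was 53.8% with a 1 bp overlap, 18.95% with the strongest peaks of replicate 1 in equal number and 55.7% with fold above the common median. Spearman's rho was 0.45 with a 1 bp overlap. The share of shared peaks at gene ends was 40.0% within 5000 bp and 42.7% with fold above the median, and 5.96 to 15.1% in single replicates. The 2 lists past the threshold became 0 with gene bodies, 0 with the strongest peaks of replicate 1, 0 to 1 in single replicates and 7 against the housekeeping list, where the 7 lay lower. In percentage points above other genes, the lysosome list was no longer past the threshold with gene bodies (17.3), the strongest peaks (20.7), single replicates (10.6 to 23.4) and the housekeeping list (3.33). The forkhead list was not with gene bodies (17.3), the strongest peaks (11.4), replicate 1 alone (13.9, against 33.2 with replicate 2 alone) and the housekeeping list (13.1). With the strongest peaks ranked by −log10 q, 2 lists passed, the same forkhead (38.9) and lysosome (26.0) lists. Directions turned for 7 of the lists that the report does not call, 4 of which lay lower past the threshold against the housekeeping list (alternative activation, macrophage identity, regulatory T cell and T cell markers). LC3-associated phagocytosis was at -1.52 against the housekeeping list, and phagocytic receptors were at -14.6 there and at -8.68 with the strongest peaks. Alternative activation was at 2.61 with 5000 bp windows, 2.50 with gene bodies and -15.2 to 2.79 in single replicates. Interferon response was at 0.289, 0.65 and -0.815 to 1.40 in the same order. Macrophage identity was at 6.84 and 6.61 with the first 2 of these. T cell markers were at 6.13, 2.32 and -13.3 to 13.9, and the regulatory T cell list was at -13.3 to 6.77 in single replicates. The causes were not tested. The motif alternatives and the motif test were not run, for want of sequence. The results rest on 2 replicates of unstated origin without the IgG library. Sites below the smallest pileups called, 10 and 13 fragments, could not be listed.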

Other observations

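Gene families defined by symbol, chosen after the lists were seen, spread much further than the fixed lists. Olfactory receptor genes, which are expressed in sensory neurons, had a site in both replicates in 40 of 1106 cases (3.62%, 95% exact interval 2.60 to 4.89%). Vomeronasal receptor genes had one in 9 of 353 (2.55%, 1.17 to 4.78%), against 63.2% of other genes (Fisher's exact test, adjusted p = 8.4e-132 over 14 families). Both families hold many similar copies, whose reads can be shared. C-type lectin genes, many of them receptors of myeloid cells, had a site in 7 of 33 (21.2%, 9.0 to 38.9%; adjusted p = 9.19e-06 by Fisher's exact test) and chemokine ligand genes in 10 of 32 (31.2%, 16.1 to 50.01%; adjusted p = 0.00118 by Fisher's exact test). Windows 20 kb outside the genes of these families also held peaks less often than the 21.9% of all genes. The shares were 6.51% for olfactory, 8.78% for vomeronasal, 12.1% for C-type lectin and 6.25% for chemokine ligand genes. A low regional density of peaks was therefore not separated from a lack of sites at the gene ends.

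Families used by most cells lay above other genes. Rab genes of vesicle traffic had a site in 49 of 58 (84.5%; adjusted p = 0.00116), ribosomal protein genes in 63 of 80 (78.8%; adjusted p = 0.00567), proteasome genes in 38 of 49 (77.6%; adjusted p = 0.0419) and vacuolar ATPase genes in 19 of 22 (86.4%; adjusted p = 0.0419), all by Fisher's exact test. Of the developmental regulators, Tbx genes had a site in 12 of 13 (92.3%; adjusted p = 0.0419), whereas Sox (16 of 19, adjusted p = 0.0805) and Pax genes (8 of 9, adjusted p = 0.21) did not pass Fisher's exact test. Keratin genes were at 27 of 49 and Toll-like receptor genes at 6 of 12, neither past Fisher's exact test (adjusted p = 0.36 and 0.41).

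Chromosome X carried 121 peaks per Mb in replicate 1, against 178 to 281 on the autosomes, and 23.4 per Mb in replicate 2, against 28.6 to 50.3.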
